A study of Arabidopsis thaliana with 8 samples.

How the data were processed

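RNA had been isolated from roots of Arabidopsis thaliana seedlings of the wild type Col and of cml24-2, a mutant line of CML24 (AT5G37770, also TCH2), which encodes a calmodulin-like calcium-binding protein. Per the labels, 6-d-old seedlings grown in nutrient solution were given 0 or 10 µM AlCl3 for 6 h, RNA was prepared with an RNeasy kit, and sequencing was on the BGISEQ-500 platform. There were 8 libraries in 4 groups of n = 2: wild type and cml24-2, each without and with Al. The labels do not say whether the 2 libraries of a group came from separate cultures, so p-values measure only the spread between these samples.

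The deposited files give, for each gene, the expected_count, the length and the FPKM that the authors obtained with RSEM, per the submitters' processing notes. The deposited expected counts are estimated numbers of reads per gene, not scaled. The authors' FPKM divide the expected count by the listed gene length and by the library's assigned reads, and recomputed totals were 1.0005 to 1.00095 times the column totals of the counts. Genes with an FPKM under 0.01 are not listed and were taken as 0. The version of RSEM, the aligner and the genome build are not given in the sources used here. Of the expected counts, 89.1 to 89.5% per library were whole numbers within 0.005, and the rest carry reads shared between genes. Gene names came from a RefSeq annotation table of Arabidopsis, which matched 24086 of 24279 gene identifiers. The remaining 193 were chloroplast and mitochondrial genes.

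Expected counts were rounded to whole numbers and tested with edgeR 4.0.16 (R 4.3.3): TMM factors (0.984 to 1.03), filterByExpr by group, a quasi-likelihood fit with a mean per group over all 8 libraries (4 residual degrees of freedom), and quasi-likelihood F tests. The contrasts were Al against no Al in each genotype, cml24-2 against wild type without and with Al, and the genotype by Al interaction. Calls had a Benjamini-Hochberg adjusted p under 0.05 over the 20262 genes tested. Log2 fold changes are given with standard errors (SE) derived from the F statistic, and levels as CPM, counts scaled to the normalized library total, with standard deviations (SD), n = 2. For a gene with 0 counts in a group, the ratio is a lower bound from a floor of 3 counts in its 2 libraries together, and for 1 to 3 counts it is a ratio with a 95% counting interval. Intervals and floors cover counting error only. Library totals were 11743400 to 12188900 expected counts, which puts 3 counts in a single library at 0.246 to 0.255 CPM. The common biological coefficient of variation was 11.0%.

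There were 21 gene lists, chosen before the data were examined together with the tests, the contrasts and the alternatives below except 1: aluminium resistance, calmodulin and calmodulin-like, phosphate starvation, iron deficiency, xyloglucan and expansin cell wall, glutathione transferase and oxidative stress, auxin, ethylene, jasmonate, salicylate and immunity, WRKY factors, abscisic acid and cold, heat shock, phenylpropanoid and lignin, nitrate, cell cycle, DNA damage, shoot photosynthesis (markers of another tissue), root hair cells, endodermis and root cap cells, and xylem and phloem cells. They hold 355 distinct genes, of which 331 were tested. Lists were tested with camera (limma 3.58.1) on log2 CPM, with a preset inter-gene correlation of 0.01 and also with the correlation estimated for each list, and p-values were adjusted over the 21 lists. Members past the gene test were counted with adjustment over all genes and also over the list alone.

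The rule for named genes, also written beforehand, took CML24, all aluminium-resistance members, up to 4 members of each list, and the 10 largest changes in each direction with an adjusted p under 0.05, libraries that did not overlap and a mean FPKM of 2 or more in the higher group. For the interaction it took the 6 largest in each direction with an adjusted p under 0.05 and a mean FPKM of 2 or more in the highest group. Any list member may serve as an example. The few genes outside the rule are marked in the text as chosen after their values were seen.

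Alternatives were DESeq2 1.42.0 (Wald test), RLE size factors, no low-count filter (a count of at least 1), a strict filter (1 CPM in at least 4 libraries), only the 4 libraries compared, the replicate number as a block, limma on log2(FPKM + 1) and log2(FPKM + 0.1) with an FPKM of 1 in at least 2 libraries, and each library left out in turn. Testing the lists with each library left out was added after the data were seen. Counts were also simulated once per pairwise contrast at the observed depth, with genes drawn independently and 1 spread per gene pooled over the 4 groups. The wild-type controls were further apart than the other pairs, which a pooled spread does not carry. With known changes of 1.5, 2 and 4 fold in 66 or 67 genes each, edgeR recovered 22.4, 74.6 and 100% for Al in wild type, and 2.99, 34.3 and 97.0% for the interaction. False genes made up 8.39 to 10.9% of simulated calls in the 4 pairwise contrasts, above the nominal share.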

Results

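Roots of wild type and of cml24-2 were compared after 6 h with 0 or 10 µM Al, with n = 2 libraries in each of the 4 groups, and 20262 genes were tested. CML24 itself was at 72.9 ± 41.5 CPM (SD, n = 2) in wild type without Al, 41.3 ± 2.81 with Al, 154 ± 50.2 in cml24-2 without Al and 113 ± 25.8 in cml24-2 with Al. The labels do not give the kind of allele, so these levels do not test the genotype labels. Its expected counts were 549 and 1238, 522 and 454, 2258 and 1405, and 1569 and 1136 in the same order. The log2 difference of cml24-2 from wild type was 1.08 (SE 0.36, edgeR adjusted p = 0.079) without Al and 1.45 (SE 0.37, adjusted p = 0.045) with Al. The latter call ended under 10 of 16 alternatives: without any 1 library of the comparison (adjusted p = 0.22 and 0.23 without wild-type Al replicates 1 and 2, 0.21 and 0.11 without cml24-2 Al replicates 1 and 2), without cml24-2 control replicate 1 or 2 (0.051 each), with DESeq2 (0.066), with the replicate block (0.071) and with limma on log2(FPKM + 1) (0.063) or log2(FPKM + 0.1) (0.069). The former was called without wild-type control replicate 2 (0.0020). The response of CML24 to Al was not called in wild type (log2 fold change -0.82, adjusted p = 0.091) or in cml24-2 (-0.44, adjusted p = 0.34), although that in wild type was called without wild-type control replicate 1 (adjusted p = 0.0012).

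In wild type, Al raised ALMT1, the malate channel of aluminium exclusion, from 0.933 ± 0.198 to 50.1 ± 4.40 CPM (SD, n = 2; log2 fold change 5.74, SE 0.28, edgeR adjusted p = 8.5e-07). MATE, a citrate transporter, rose from 8.22 ± 0.406 to 35.3 ± 0.124 CPM (2.1, SE 0.13), and STOP1, the zinc finger factor that controls both, from 189 ± 2.21 to 338 ± 4.51 CPM (0.84, SE 0.09). RAE1, an F-box protein acting on STOP1, rose by 2.80 (SE 0.13), the polygalacturonase inhibitor PGIP1 by 2.58 (SE 0.13), CAMTA2 by 1.64, GDH2 by 1.46, SAUR55 by 1.21, the vacuolar transporter ALS1 by 0.97, NIP1;2 by 0.84 and STOP2 by 0.58 on the log2 scale. Of the 18 measured aluminium-resistance genes, 13 rose, 1 fell (XTH31, -0.72) and 4 did not pass, with 13 and 2 adjusted over the list alone. The median log2 fold change was 1.09 (camera adjusted p = 8.6e-05, adjusted p = 0.19 with an estimated correlation). Among the rises, the call of ALS3 was lost under 9 of 16 alternatives, DESeq2 being one (adjusted p = 0.21).

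Large rises in wild type included PRX52, a peroxidase (0.801 ± 0.549 to 111 ± 10.8 CPM, 7.08, SE 0.24), and LEA4-5, a late embryogenesis abundant protein (0.702 to 79.0 CPM, 6.82, SE 0.68). AT1G71140, of the MATE efflux family, went from 0.122 to 26.9 CPM, 221-fold by counts (95% counting interval 75.4 to 1076). The transcription factor gene CIB1 had no counts without Al and 9.46 ± 0.709 CPM with it, at least 77.8-fold by a floor of 3 counts over both control libraries together, although its counts were partly shared with other genes in 4 libraries. AT3G19430 fell from 246 ± 37.5 to 2.32 ± 0.828 CPM (-6.72, SE 0.20). Across all genes, edgeR called 5089 higher and 5238 lower with Al, 1717 and 2359 of them by at least 2-fold.

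Glutathione transferase and oxidative-stress genes formed the list with the smallest p in wild type: 22 of 26 rose and 1 fell (23 and 1 over the list alone). The median was 1.64 (camera adjusted p = 1.1e-08, adjusted p = 0.22 with an estimated correlation). Examples were the glutathione transferases GSTU22 (2.24 ± 0.922 to 134 ± 3.32 CPM, 5.90, SE 0.20), GSTU8 (4.28, SE 0.19) and GSTU24 (3.39, SE 0.16). Abscisic acid and cold genes rose in 12 of 17 and fell in 0 (12 and 1 over the list alone). The median was 1.44 (camera adjusted p = 1.4e-04, adjusted p = 0.40 with an estimated correlation). Among them were the phosphatases ABI2 (2.45, SE 0.13) and ABI1 (1.60, SE 0.12) and the stress marker RD29A (83.5 ± 3.64 to 372 ± 53.5 CPM, 2.16, SE 0.12). Ethylene genes rose in 9 of 20 and fell in 2 (10 and 2 over the list alone). The median was 0.51 (camera adjusted p = 0.027, adjusted p = 0.37 with an estimated correlation). They included the synthesis genes ACS11 (3.23) and ACO4 (1.45) and the signalling F-box gene EBF2 (1.11).

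Markers of several root cell types and of dividing cells fell in wild type with Al. All 8 root-hair genes fell. The median was -2.98 (camera adjusted p = 8.6e-05, adjusted p = 0.22 with an estimated correlation). Examples were COBL9 (57.0 ± 7.06 to 3.27 ± 0.639 CPM, -4.12, SE 0.20) and the expansins EXPA7 (-4.08) and EXPA18 (-4.12). Cell-cycle genes fell in 11 of 12. The median was -0.96 (camera adjusted p = 3.9e-04, adjusted p = 0.37 with an estimated correlation). Examples were the replication clamp PCNA1 (-1.29) and the cytokinesis syntaxin KNOLLE (-1.004). Endodermis and root-cap genes fell in 6 of 7 and rose in 1. The median was -1.10 (camera adjusted p = 0.023, adjusted p = 0.37 with an estimated correlation). Examples were the Casparian-strip genes CASP1 (-2.52) and ESB1 (-2.14). Xyloglucan and expansin genes fell in 13 of 20 and rose in 4 (14 and 4 over the list alone). The median was -1.38 (camera adjusted p = 0.010, adjusted p = 0.37 with an estimated correlation). Of the xyloglucan transglucosylases, XTH15 fell by 1.98 and XTH24 rose from 56.5 to 646 CPM (3.52). Iron-deficiency genes fell in 13 of 22 and rose in 3. The median was -0.63 (camera adjusted p = 0.046, adjusted p = 0.73 with an estimated correlation). The uptake genes IRT1 (-3.27) and FRO2 (-3.36) fell and the iron-phloem transporter OPT3 rose (2.08). Shoot photosynthesis markers fell in 5 of 13, PSBO1 by 1.79 and LHCB6 by 1.78. The median was -1.78 (camera adjusted p = 0.028, adjusted p = 0.73 with an estimated correlation).

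The other 11 lists were not called in wild type with Al. Salicylate and immunity genes rose in 3 of 9 and fell in 0 (median 0.56, camera adjusted p = 0.063), among them EDS1 (0.97) and NPR1 (0.71). WRKY factors rose in 8 of 17 and fell in 3 (median 0.74, adjusted p = 0.064), with WRKY75 at 4.1 and WRKY45 at 3.54. Nitrate genes fell in 6 of 13 and rose in 2 (8 and 2 over the list alone, median -0.51, adjusted p = 0.091), the transporter NRT1.1 by 1.39 and the repressor HRS1 by 1.28 on the log2 scale. Heat-shock genes rose in 4 of 12 and fell in 1 (median 0.38, adjusted p = 0.13), as HSP70 did (1.1). Calmodulin-like genes rose in 10 of 27 and fell in 6 (10 and 7 over the list alone, median 0.20, adjusted p = 0.19), and CML47 went from 1.22 ± 0.378 to 88.4 ± 6.96 CPM (6.17, SE 0.20). Phosphate-starvation genes rose in 5 of 18 and fell in 2 (median 0.19, adjusted p = 0.24), with the ribonuclease RNS1 at 2.70. Auxin genes rose in 9 of 24 and fell in 6 (median 0.09, adjusted p = 0.54), the synthesis gene TAA1 falling by 1.71. Jasmonate genes rose in 3 of 17 and fell in 1 (adjusted p = 0.81), with a median of -0.47 and a mean of -0.09 but an upward camera direction, and DNA-damage genes rose in 3 of 7 and fell in 1 (3 and 2 over the list alone, adjusted p = 0.81), with a median of -0.12 and a mean of 0.04. Xylem and phloem genes rose in 1 of 9 and fell in 0 (0 and 0 over the list alone, median -0.13, adjusted p = 0.81). Phenylpropanoid genes rose in 5 of 19 and fell in 4 (median -0.06, adjusted p = 0.84), where the hydroxylase F5H fell from 40.2 ± 2.46 to 2.11 ± 0.535 CPM (-4.24, SE 0.21) and CAD5 rose (1.38).

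Iron genes lost their wild-type call without wild-type control replicate 2 (adjusted p = 0.16) or wild-type Al replicate 2 (0.077), ethylene genes without wild-type control replicate 1 (0.29), and shoot photosynthesis markers without wild-type control replicate 2 (0.18) or wild-type Al replicate 2 (0.10). The shoot median was -2.46 with 12 of 13 lower without wild-type control replicate 1, -0.16 without replicate 2, -3.46 without wild-type Al replicate 1 and -1.15 without replicate 2. Without wild-type control replicates 1 and 2 and wild-type Al replicates 1 and 2 in that order, members past the test were 14, 9, 8 and 7 lower for iron, 9, 14, 9 and 7 higher and 5, 2, 0 and 1 lower for ethylene (median 1.05 without wild-type control replicate 2), 8, 11, 7 and 7 higher and 10, 3, 4 and 3 lower for calmodulin-like genes, 3, 5, 1 and 3 higher and 7, 0, 0 and 0 lower for jasmonate, and 2, 6, 2 and 4 higher for phosphate. Nitrate genes were called without wild-type control replicate 1 (0.046), and salicylate (8 of 9 rose, 0.0012), WRKY (12 of 17 rose, 6.5e-04) and calmodulin-like genes (0.025) without replicate 2. The summed shoot markers were at 99.2 and 186 CPM in the wild-type control libraries and 75.1 and 31.6 CPM with Al.

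**Figure D1:**
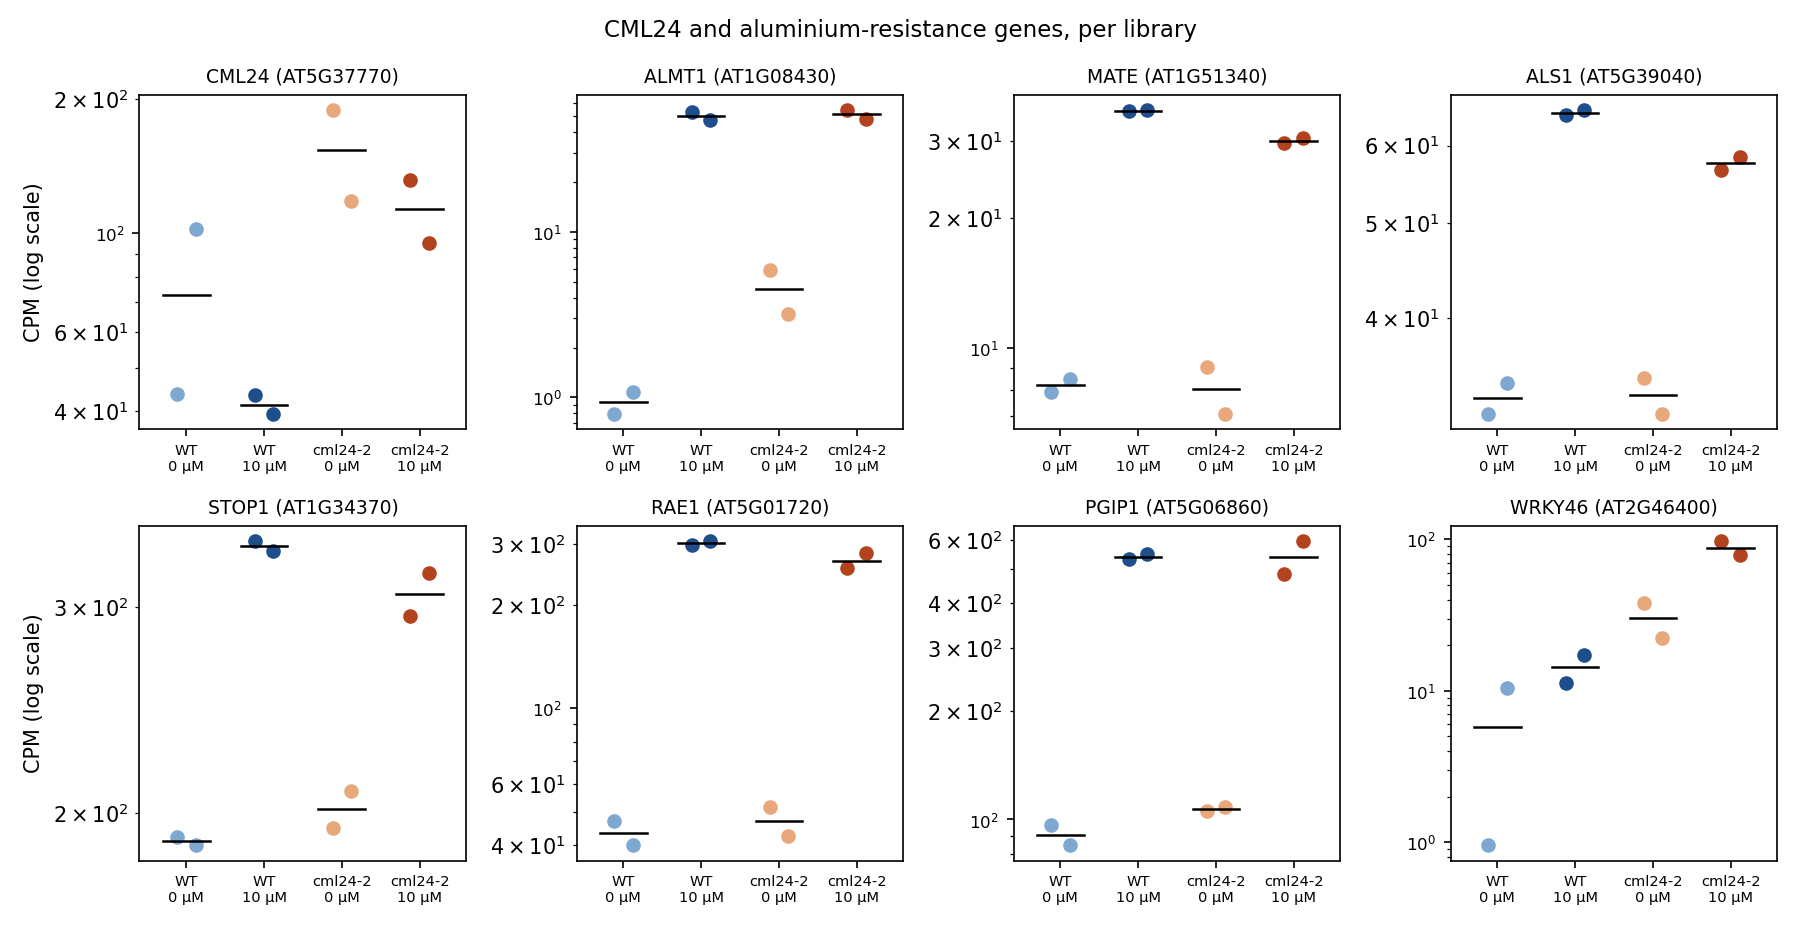
CPM of CML24 and 7 aluminium-resistance genes in each library on a log scale. Points are libraries and bars are group means, n = 2.

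In cml24-2, ALMT1 rose from 4.53 ± 1.89 to 51.2 ± 4.24 CPM with Al (SD, n = 2; log2 fold change 3.5, SE 0.22, edgeR adjusted p = 5.5e-06) and MATE from 8.05 ± 1.40 to 30.1 ± 0.537 CPM (1.90, SE 0.13). STOP1 rose by 0.61 (SE 0.09), RAE1 by 2.52 (SE 0.13), PGIP1 by 2.33, CAMTA2 by 1.36, GDH2 by 1.09 and ALS1 by 0.79 on the log2 scale. The log2 fold changes of NIP1;2 (0.25, adjusted p = 0.17) and STOP2 (0.23, adjusted p = 0.16) did not pass. Of the 18 aluminium-resistance genes, 12 rose, 1 fell and 5 did not pass (13 and 2 over the list alone). The median was 0.83 (camera adjusted p = 5.8e-05, adjusted p = 0.18 with an estimated correlation). Among the rises, the call of WRKY46 was lost under 10 of 16 alternatives, DESeq2 being one (adjusted p = 0.27), and that of ALS3 under 2. The gene that fell was STAR1 (-0.41, adjusted p = 0.048), a call lost under 13 of 16 alternatives, among them DESeq2 (adjusted p = 0.22) and leaving out cml24-2 control replicate 2 (0.25) or cml24-2 Al replicate 1 (0.11) or 2 (0.18).

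Large single changes with Al in cml24-2 included CML47, from 1.85 ± 0.123 to 101 ± 13.8 CPM (5.77, SE 0.18), the ubiquitin ligase gene PUB54, from 1.17 to 51.8 CPM (5.45, SE 0.26), and AT3G22910, of the calcium ATPase family, from 7.25 ± 1.58 to 260 ± 49.7 CPM (5.16, SE 0.21). AT3G19430 fell from 125 ± 3.98 to 0.335 CPM (-8.50, SE 0.26). The genes called were 4313 higher and 4717 lower, 1233 and 1823 of them by at least 2-fold.

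Glutathione transferase genes rose in 19 of 26 and fell in 2. The median was 1.17 (camera adjusted p = 4.5e-06, adjusted p = 0.22 with an estimated correlation). Examples were GSTU24 (3.64, SE 0.18) and GSTU22 (17.45 ± 2.41 to 135 ± 0.405 CPM, 2.96, SE 0.16). Ethylene genes rose in 12 of 20 and fell in 1. The median was 0.95 (camera adjusted p = 6.3e-04, adjusted p = 0.20 with an estimated correlation). Examples were ACS11 (2.95) and the receptor ERS1 (0.70). Abscisic acid and cold genes rose in 12 of 17 and fell in 0. The median was 1.01 (camera adjusted p = 5.7e-04, adjusted p = 0.55 with an estimated correlation). ABI2 was at 2.13 and RD29A at 1.42. Salicylate and immunity genes rose in 6 of 9 and fell in 0. The median was 0.82 (camera adjusted p = 0.014, adjusted p = 0.60 with an estimated correlation). Examples were EDS1 (1.36) and EDS5, a salicylate precursor transporter (1.01).

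Root-hair genes fell in 8 of 8. The median was -2.75 (camera adjusted p = 5.8e-05, adjusted p = 0.20 with an estimated correlation). Examples were COBL9 (23.9 ± 3.97 to 2.01 ± 0.470 CPM, -3.57) and EXPA7 (-4.38). Cell-cycle genes fell in 11 of 12. The median was -0.78 (camera adjusted p = 2.5e-04, adjusted p = 0.34 with an estimated correlation), and PCNA1 fell by 1.09. Endodermis and root-cap genes fell in 6 of 7. The median was -1.24 (camera adjusted p = 0.0021, adjusted p = 0.20 with an estimated correlation). CASP1 fell by 3.18 and the root-cap factor BRN2 by 1.26. Nitrate genes fell in 10 of 13 and rose in 1 (11 and 1 over the list alone). The median was -0.65 (camera adjusted p = 0.014, adjusted p = 0.60 with an estimated correlation). NRT1.1 fell by 1.71 and HRS1 by 1.56, and the nitrate reductase NIA1 rose (1.47). The nitrate call ended without cml24-2 control replicate 2 (adjusted p = 0.056). Without cml24-2 control replicates 1 and 2 and cml24-2 Al replicates 1 and 2 in that order, nitrate genes lower were 9, 6, 6 and 7, salicylate genes higher 4, 3, 3 and 4, ethylene genes higher 11, 8, 8 and 11 and abscisic acid genes higher 8, 9, 9 and 11.

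The remaining 12 lists were not called in cml24-2 with Al. Calmodulin-like genes rose in 11 of 27 and fell in 2 (median 0.09, camera adjusted p = 0.057), with CML41 at 3.38 (SE 0.16). Phosphate genes rose in 7 of 18 and fell in 2 (median 0.41, adjusted p = 0.079), iron genes fell in 9 of 22 and rose in 2 (10 and 3 over the list alone, median -0.54, adjusted p = 0.079), and heat-shock genes rose in 6 of 12 and fell in 1 (median 0.49, adjusted p = 0.079). FRO2 fell by 2.15 and its regulator FIT by 2.14, while RNS1 was at 3.52 and the coactivator MBF1C at 1.17. Jasmonate genes rose in 1 of 17 (CYP94C1, a jasmonate hydroxylase, 1.72) and fell in 0 (median 0.54, adjusted p = 0.13), and WRKY factors rose in 7 of 17 and fell in 3 (median 0.48, adjusted p = 0.13), WRKY45 by 3.11. Shoot markers fell in 4 of 13 (median -0.80, adjusted p = 0.15), at 206 and 310 CPM in sum without Al and 137 and 175 CPM with it. Auxin genes rose in 11 of 24 and fell in 7 (12 and 7 over the list alone, median 0.45, adjusted p = 0.18), TAA1 falling by 1.54. Xyloglucan and expansin genes rose in 5 of 20 and fell in 7 (median -0.24, adjusted p = 0.36), with XTH24 at 3.04 and XTH15 at -1.64. Xylem and phloem genes fell in 1 of 9 (median -0.18, adjusted p = 0.36), namely VND7, a xylem vessel factor (-1.12), whose call was lost without cml24-2 control replicate 1 (adjusted p = 0.060) or cml24-2 Al replicate 2 (0.090) and with DESeq2 (0.10). Phenylpropanoid genes rose in 5 of 19 and fell in 3 (median 0.10, adjusted p = 0.53), F5H by 2.53. DNA-damage genes rose in 1 of 7 (0 over the list alone) and fell in 0 (median -0.22, adjusted p = 0.99). That gene was SMR7, a call lost under 11 of 16 alternatives, among them DESeq2 (adjusted p = 0.30) and leaving out cml24-2 control replicate 1 (0.13) or 2 (0.16) or cml24-2 Al replicate 1 (0.14) or 2 (0.12). Calmodulin-like genes were called without wild-type control replicate 1 (adjusted p = 0.047) or 2 (0.044), cml24-2 control replicate 1 (0.0093) or cml24-2 Al replicate 2 (0.027), iron and heat-shock genes without cml24-2 control replicate 1 (0.012 and 0.022) or cml24-2 Al replicate 2 (0.042 and 0.027), and phosphate (14 of 18 rose, 5.6e-04) and jasmonate genes (0.039) without cml24-2 Al replicate 2.

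The responses of the genotypes to Al overlapped. Of the genes called, 3622 were higher in both (1083 expected by chance) and 3899 lower in both (1219 expected), 25 were called in opposite directions, 2781 only in wild type and 1484 only in cml24-2. Log2 fold changes correlated at r = 0.86 across genes. Of the genes called in both, 64.6% had the larger change in wild type, with median absolute log2 fold changes of 0.92 and 0.81, while GSTU24 (3.39 and 3.64) and CML41 (2.88 and 3.38) were among those whose larger value was in cml24-2.

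**Figure D2:**
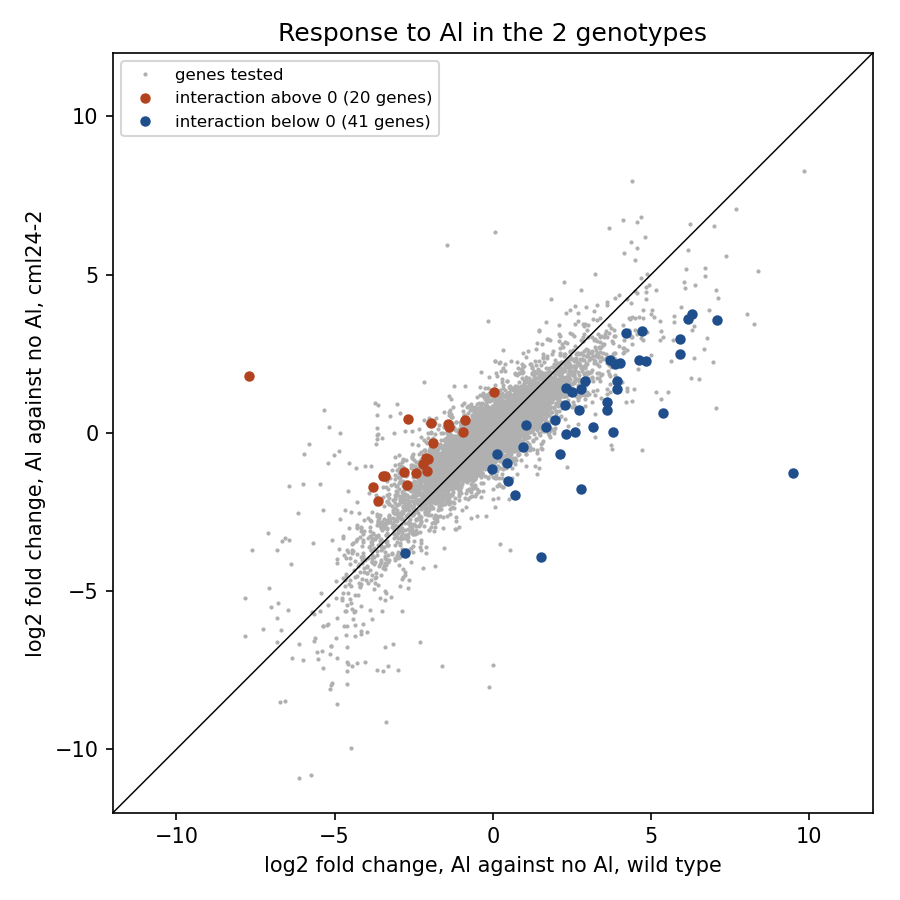
Log2 fold change with Al in wild type and in cml24-2 for all genes tested. Coloured points are the genes with a called interaction and the line marks equal values.

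Without Al, genes of phosphate starvation were lower in cml24-2 than in wild type. SQD2, which makes sulfolipids that replace phospholipids, was at 650 ± 69.6 CPM in wild type and 255 ± 17.8 CPM in cml24-2 (SD, n = 2; log2 fold change -1.35, SE 0.18, edgeR adjusted p = 0.0028), the phosphate sensor gene SPX1 at 447 ± 57.0 and 192 ± 0.327 CPM (-1.22, SE 0.18), the exporter PHO1;H1 at 158 ± 11.5 and 68.9 ± 6.60 CPM (-1.20, SE 0.17) and the acid phosphatase PAP17 at 139 ± 7.92 and 67.4 ± 4.65 CPM (-1.05, SE 0.15). Of the 18 measured, 12 were lower and 0 higher (14 and 0 over the list alone). The median was -0.78 (camera adjusted p = 9.6e-08, adjusted p = 0.52 with an estimated correlation). ALMT1 was higher in cml24-2 without Al (2.27, SE 0.35, adjusted p = 0.0053).

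WRKY factors were higher in 10 of 17 and lower in 0 (12 and 0 over the list alone). The median was 1.19 (camera adjusted p = 1.4e-05, adjusted p = 0.52 with an estimated correlation). WRKY48 was at 16.6 ± 12.9 and 123 ± 39.1 CPM (2.90, SE 0.43), WRKY28 at 4.16 and 11.6 CPM (1.48, SE 0.15) and WRKY15 differed by 0.64 (SE 0.10). DNA-damage genes were higher in 3 of 7. The median was 0.59 (camera adjusted p = 9.1e-04, adjusted p = 0.44 with an estimated correlation). An example was GMI1, a double-strand break repair gene (13.9 ± 0.633 and 39.0 ± 2.28 CPM, 1.48, SE 0.12). Root-hair genes were lower in 5 of 8 (7 over the list alone). The median was -0.90 (camera adjusted p = 0.0014, adjusted p = 0.44 with an estimated correlation). COBL9 was at 57.0 and 23.9 CPM (-1.25, SE 0.16).

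Cell-cycle genes were lower in cml24-2 without Al in 3 of 12, namely KNOLLE, CDC20.1 and CYCB1;2, calls lost with DESeq2 (adjusted p = 0.11, 0.15 and 0.051) and under 10, 12 and 6 of 16 alternatives. The median was -0.32 (camera adjusted p = 0.017, adjusted p = 0.58 with an estimated correlation). Auxin genes were higher in 7 of 24 and lower in 1. The median was 0.31 (camera adjusted p = 0.013, adjusted p = 0.44 with an estimated correlation). Ethylene genes were higher in 3 of 20 (7 over the list alone). The median was 0.73 (camera adjusted p = 0.017, adjusted p = 0.44 with an estimated correlation). Jasmonate genes were higher in 3 of 17. The median was 0.66 (camera adjusted p = 0.019, adjusted p = 0.72 with an estimated correlation). An example was CYP94B3, which inactivates jasmonoyl-isoleucine (11.5 ± 3.19 and 65.2 ± 34.1 CPM, 2.51, SE 0.36). Glutathione transferase genes were higher in 6 of 26 and lower in 1 (9 and 2 over the list alone). The median was 0.38 (camera adjusted p = 0.026, adjusted p = 0.60 with an estimated correlation), and GSTU22 was higher by 2.96 (SE 0.21). Beside these groups, shoot photosynthesis markers had a median of 0.92, with 0 of 13 passing singly (camera adjusted p = 0.022, adjusted p = 0.65 with an estimated correlation). They summed to 99.2 and 186 CPM in wild type against 206 and 310 CPM in cml24-2.

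Large single differences between the genotypes without Al included AT4G29200 (59.7 ± 18.6 in wild type and 0.377 ± 0.296 CPM in cml24-2, -7.27, SE 0.45), the orphan gene QQS (24.4 ± 7.14 and 0.713 ± 0.295 CPM, -5.08, SE 0.33), NDB4, an alternative NAD(P)H dehydrogenase (0.691 ± 0.191 and 22.1 ± 4.38 CPM, 4.98, SE 0.32), and AT1G64795 (1 count in wild type, 18.6 CPM in cml24-2, 460-fold by counts, 95% counting interval 82.2 to 18216). AT5G60250 was at 0.810 and 18.9 CPM (4.53, SE 0.20), and CBL8, a calcineurin B-like calcium sensor, at 3.52 and 0.378 CPM (-3.19, SE 0.38). edgeR called 1501 genes higher and 1115 lower in cml24-2 without Al, 618 and 336 by at least 2-fold. These counts were 987 and 770 with DESeq2, 1308 and 1239 with RLE size factors, 1146 and 1263 with limma on log2(FPKM + 1) and 1062 and 1061 on log2(FPKM + 0.1). They fell to 481 and 407 with only the 4 libraries compared, which kept 873 of the 2604 calls tested there.

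Lists not called between the genotypes without Al were xyloglucan and expansin genes (3 of 20 higher and 8 lower, 5 and 9 over the list alone, median -0.28, camera adjusted p = 0.17), with XTH26 at -2.78 and XTH14 at -1.59, and iron genes (3 of 22 higher and 1 lower, median 0.25, adjusted p = 0.17). Aluminium-resistance genes were higher in 3 of 18 and lower in 0 (median 0.10, adjusted p = 0.27): ALMT1, WRKY46 (2.41) and NIP1;2 (0.53). The call of WRKY46 was lost under 10 of 16 alternatives, with DESeq2 (adjusted p = 0.18) and without any 1 library but the wild-type controls (0.067 to 0.18), and that of NIP1;2 under 13 of 16, with DESeq2 (0.27) and without any 1 library but wild-type control replicate 2 (0.069 to 0.20). Salicylate genes were higher in 1 of 9 and lower in 1 (4 and 1 over the list alone, median 0.41, adjusted p = 0.27), endodermis and root-cap genes in 0 of 7 (3 higher over the list alone, median 0.38, adjusted p = 0.39), and calmodulin-like genes higher in 3 of 27 and lower in 1 (3 and 3 over the list alone, median 0.14, adjusted p = 0.42), as in CML36 (0.84) and CML35 (0.81). None of 12 heat-shock genes (median 0.06, adjusted p = 0.72) or 9 xylem and phloem genes (median -0.11, adjusted p = 0.72) passed. Phenylpropanoid genes were higher in 2 of 19 (median -0.05, adjusted p = 0.72), nitrate genes higher in 1 of 13 and lower in 1 (3 and 2 over the list alone, median 0.06, adjusted p = 0.92), and abscisic acid genes higher in 1 of 17 and lower in 2 (2 and 3 over the list alone, adjusted p = 0.94), with a median of 0.16 and a mean of 0.09 against a downward camera direction.

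Without wild-type control replicate 1 the calls of glutathione transferase (adjusted p = 0.20), auxin (0.088), jasmonate (0.60) and shoot photosynthesis genes (0.53) between the genotypes without Al ended, as did those of jasmonate genes without cml24-2 control replicate 1 (0.14), shoot genes without cml24-2 control replicate 2 (0.12) and cell-cycle genes without wild-type control replicate 2 (0.067), while calmodulin-like (0.0086), iron (0.0044) and salicylate genes (0.0044) were called without wild-type control replicate 2 and iron genes also without cml24-2 control replicate 1 (0.013). Counts of genes higher and lower were 1078 and 1309 without wild-type control replicate 1, 1898 and 1162 without replicate 2, 516 and 291 without cml24-2 control replicate 1, 777 and 393 without replicate 2, 997 and 684 without wild-type Al replicate 1, and 993 and 684 without replicate 2, and phosphate genes lower in cml24-2 went to 8 without wild-type control replicate 2, to 6 without cml24-2 control replicate 1 and to 5 without replicate 2, and WRKY factors higher to 3 and 4 without the latter 2. Without cml24-2 control replicates 1 and 2 in that order, cell-cycle genes lower went to 0 and 0, auxin genes higher to 0 and 2, ethylene to 1 and 0, jasmonate to 1 and 2, DNA-damage to 1 and 2, glutathione transferase to 4 and 4 and root-hair genes lower to 1 and 2, while without wild-type control replicate 2 jasmonate genes higher went to 13 and shoot genes to 9.

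With Al, ALMT1 was at 50.1 ± 4.40 CPM in wild type and 51.2 ± 4.24 CPM in cml24-2 (SD, n = 2; log2 difference 0.03, SE 0.17, 95% confidence interval -0.36 to 0.42, edgeR adjusted p = 0.94). The log2 differences of MATE (-0.23, adjusted p = 0.28), ALS1 (-0.17, adjusted p = 0.29), RAE1 (-0.17, adjusted p = 0.44) and STOP1 (-0.14, adjusted p = 0.41) did not pass either. Among the 18 aluminium-resistance genes only WRKY46 was called (2.63, adjusted p = 0.026), and that call was lost under 7 of 16 alternatives: without any 1 of the 4 libraries compared (adjusted p = 0.23, 0.15, 0.13 and 0.098 without wild-type Al replicates 1 and 2 and cml24-2 Al replicates 1 and 2), with DESeq2 (0.14) and with limma on log2(FPKM + 1) (0.056) or log2(FPKM + 0.1) (0.12). The list had a median of -0.12 and a mean of 0.08, with a downward camera direction (adjusted p = 0.27).

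Phosphate-starvation genes remained lower in cml24-2 with Al. PAP17 was at 194 ± 2.89 CPM in wild type and 85.9 ± 20.5 CPM in cml24-2 (-1.18, SE 0.15, edgeR adjusted p = 0.0042), and 8 of 18 were lower and 0 higher (15 and 1 over the list alone). The median was -0.71 (camera adjusted p = 3.3e-07, adjusted p = 0.47 with an estimated correlation). Abscisic acid and cold genes were lower in 7 of 17 and higher in 1 (8 and 2 over the list alone). The median was -0.42 and the mean -0.13 (camera adjusted p = 0.0036, adjusted p = 0.47 with an estimated correlation). An example of those lower was RD29A (372 ± 53.5 and 170 ± 14.4 CPM, -1.13, SE 0.12). The 1 higher was the cold factor CBF1 (0.464 and 9.09 CPM, 4.26, SE 1.02), whose counts were partly shared with other genes. Glutathione transferase genes were lower in 4 of 26 (5 over the list alone). The median was -0.21 (camera adjusted p = 0.021, adjusted p = 0.47 with an estimated correlation). Root-hair genes were lower in 1 of 8. The median was -0.55 (camera adjusted p = 0.020, adjusted p = 0.47 with an estimated correlation).

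Jasmonate genes were higher in 9 of 17 and lower in 0 (12 and 0 over the list alone) in cml24-2 with Al. The median was 1.41 (camera adjusted p = 2.6e-05, adjusted p = 0.47 with an estimated correlation). MYC2, the central jasmonate factor, was at 94.6 ± 3.87 and 340 ± 66.6 CPM (1.84, SE 0.33, adjusted p = 0.013), a call lost without wild-type Al replicate 1 (adjusted p = 0.13) or 2 (0.12) and cml24-2 Al replicate 1 (0.082) or 2 (0.052). Ethylene genes were higher in 7 of 20 (11 higher and 2 lower over the list alone). The median was 0.93 (camera adjusted p = 0.0011, adjusted p = 0.44 with an estimated correlation). The factor ERF104 was at 74.1 ± 2.58 and 431 ± 42.6 CPM (2.54, SE 0.27).

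WRKY factors were higher in cml24-2 with Al in 5 of 17 (8 over the list alone). The median was 0.70 (camera adjusted p = 0.0011, adjusted p = 0.47 with an estimated correlation). Auxin genes were higher in 4 of 24 (8 over the list alone). The median was 0.33 (camera adjusted p = 0.0011, adjusted p = 0.44 with an estimated correlation). Iron genes were higher in 3 of 22. The median was 0.39 (camera adjusted p = 0.0018, adjusted p = 0.50 with an estimated correlation). Salicylate genes were higher in 2 of 9 (5 over the list alone). The median was 0.55 (camera adjusted p = 0.012, adjusted p = 0.47 with an estimated correlation). Calmodulin-like genes were higher in 2 of 27. The median was 0.20 (camera adjusted p = 0.042, adjusted p = 0.59 with an estimated correlation). DNA-damage genes were higher in 4 of 7. The median was 0.49 (camera adjusted p = 0.014, adjusted p = 0.47 with an estimated correlation). Examples were PARP1, a poly(ADP-ribose) polymerase (2.54 ± 0.162 and 9.42 ± 0.313 CPM, 1.89, SE 0.20), and GMI1 (1.22, SE 0.11). Beside all of these groups, shoot photosynthesis markers were higher in 2 of 13 (7 over the list alone). The median was 2.06 (camera adjusted p = 2.6e-05, adjusted p = 0.47 with an estimated correlation). They summed to 75.1 and 31.6 CPM in wild type against 137 and 175 CPM in cml24-2.

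Large single differences with Al again included AT4G29200 (59.6 ± 4.22 and 0.419 ± 0.474 CPM, -7.12, SE 0.44), QQS (27.2 ± 0.234 and 0.921 ± 0.354 CPM, -4.87, SE 0.31), NDB4 (0.292 and 11.2 CPM, 5.19, SE 0.40) and CBL8 (3.06 and 0.251 CPM, -3.55, SE 0.42), with ABCA10, an ABC transporter, at 0.168 and 5.86 CPM (5.03, SE 0.47). The xyloglucan transglucosylase XTH4 was at 66.0 ± 3.46 and 201 ± 32.3 CPM (1.61, SE 0.12). edgeR called 938 genes higher and 687 lower in cml24-2 with Al, 502 and 252 by at least 2-fold. Of the genes called, 473 were higher in cml24-2 both without and with Al (69.5 expected by chance), 276 were lower in both (37.8 expected) and 21 changed direction, with r = 0.60 across genes.

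Lists not called between the genotypes with Al were cell-cycle genes (1 of 12 lower, median -0.21, camera adjusted p = 0.13), xylem and phloem genes (0 of 9, median -0.21, adjusted p = 0.13), nitrate genes (1 of 13 lower, 2 over the list alone, median -0.04, adjusted p = 0.20), heat-shock genes (0 of 12, median 0.11, adjusted p = 0.25), xyloglucan and expansin genes (7 of 20 higher and 1 lower, 8 and 4 over the list alone, median 0.13, adjusted p = 0.31), phenylpropanoid genes (1 of 19 higher and 1 lower, 3 and 1 over the list alone, median 0.09, adjusted p = 0.31) and endodermis and root-cap genes. In the last, 2 of 7 were lower, with a median of 0.25, a mean of -0.05 and a downward camera direction (adjusted p = 0.58).

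Counts with Al depended on single libraries: 82 genes higher and 66 lower without wild-type Al replicate 1, 84 and 82 without replicate 2, 178 and 186 without cml24-2 Al replicate 1, 197 and 93 without replicate 2, 1591 and 1197 without wild-type control replicate 1, and 1567 and 1217 without replicate 2, while jasmonate, glutathione transferase and root-hair genes past the test went to 0 without any 1 of the 4 libraries compared. Without wild-type Al replicates 1 and 2 and cml24-2 Al replicates 1 and 2 in that order, phosphate genes lower went to 1, 2, 9 and 3, abscisic acid genes lower to 2, 3, 3 and 2, and genes higher to 1, 1, 1 and 2 for ethylene, 0, 0, 0 and 1 for WRKY factors and for salicylate, 0, 0, 1 and 1 for auxin, 0, 0, 2 and 1 for iron, 0, 0, 1 and 0 for calmodulin-like genes, 2, 2, 2 and 3 for DNA damage and 2, 0, 0 and 0 for shoot markers. The calmodulin-like call ended without wild-type Al replicate 2 (adjusted p = 0.11) or cml24-2 Al replicate 1 (0.19) and with the replicate block (0.061), and the root-hair call without wild-type Al replicate 2 (0.18), while cell-cycle (0.018) and xylem and phloem genes (0.0052) were called without cml24-2 Al replicate 1.

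**Figure D3:**
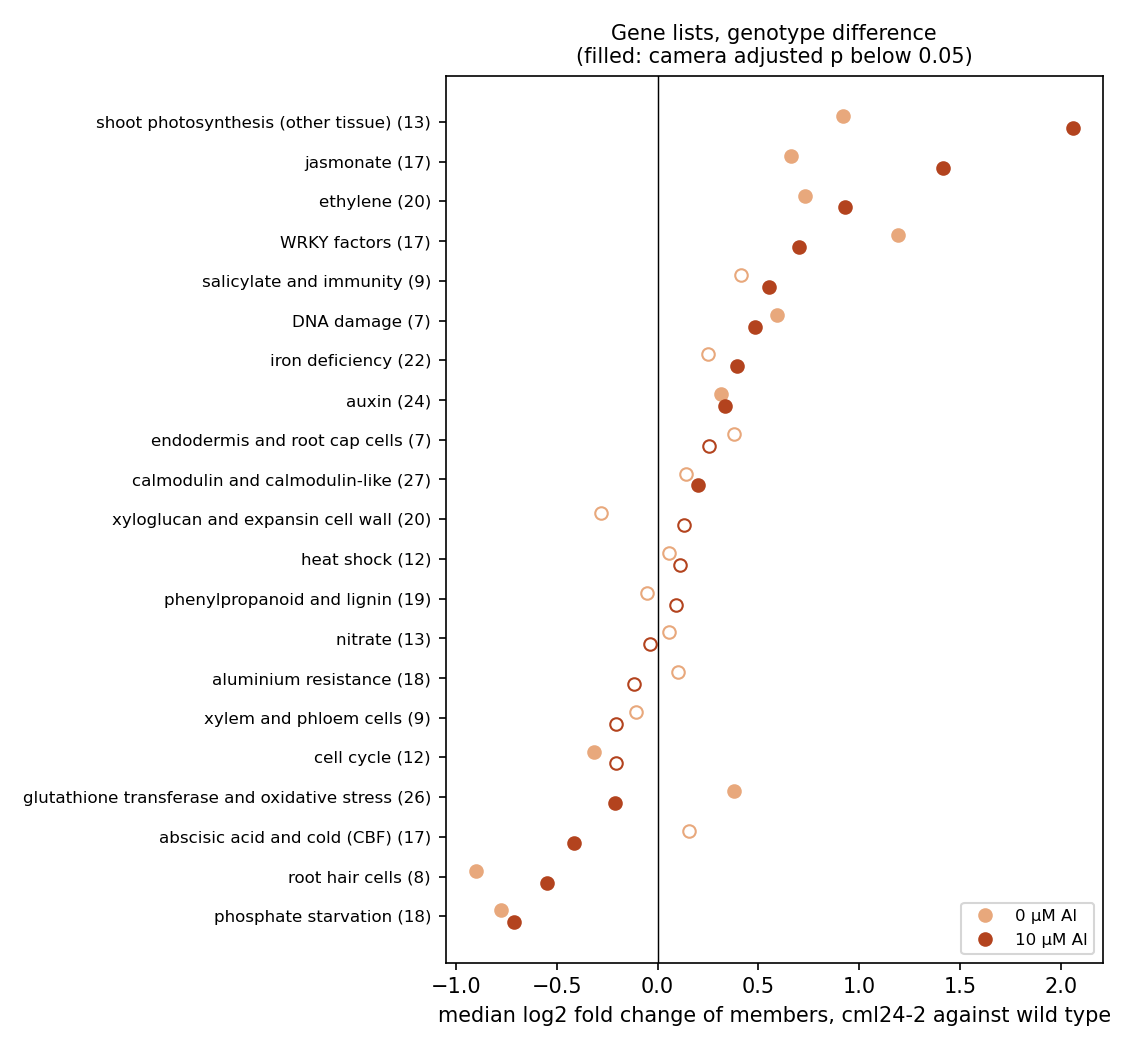
Median log2 fold change of each gene list between cml24-2 and wild type at 0 and 10 µM Al. Filled points have a camera adjusted p under 0.05, and numbers in brackets are measured members.

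The Al response differed between the genotypes for 61 genes, 20 with a positive and 41 with a negative interaction (18 and 38 by at least 2-fold). PRX52 was at 0.801 ± 0.549 and 111 ± 10.8 CPM in wild type without and with Al, and at 8.13 ± 0.811 and 96.2 ± 2.60 CPM in cml24-2 (SD, n = 2; interaction log2 fold change -3.52, SE 0.33, edgeR adjusted p = 0.0043), a call that ended with limma on log2(FPKM + 0.1) (adjusted p = 0.060). GSTU22 was at 2.24 ± 0.922, 134 ± 3.32, 17.45 ± 2.41 and 135 ± 0.405 CPM in the same order (-2.95, SE 0.26, adjusted p = 0.0026). In contrast, XTH4 was at 177 ± 3.29, 66.0 ± 3.46, 168 ± 0.145 and 201 ± 32.3 CPM (1.69, SE 0.17, adjusted p = 0.0053, lost without wild-type Al replicate 1 at 0.057). AGP22, an arabinogalactan protein, was at 120 ± 23.2, 10.7 ± 0.628, 26.7 ± 3.61 and 10.4 ± 0.433 CPM (2.12, SE 0.23, adjusted p = 0.0086), lost without wild-type Al replicates 1 (0.081) and 2 (0.078) and cml24-2 Al replicates 1 (0.064) and 2 (0.066).

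Of the 41 genes with a negative interaction, 37 rose with Al in wild type and 38 were higher in cml24-2 without Al, with 35 doing both. Of the 20 with a positive interaction, 19 fell with Al in wild type and 14 were lower in cml24-2 without Al, with 13 doing both. The wild-type control libraries enter all of these contrasts, so these pairs are not independent. The interaction of ALMT1 was -2.24 (SE 0.40, adjusted p = 0.061), called with DESeq2 (adjusted p = 1.4e-04), without wild-type control replicate 2 (0.047) and without cml24-2 control replicate 2 (0.030). The interactions of MATE (-0.20, adjusted p = 0.72), RAE1 (-0.28, adjusted p = 0.57), ALS1 (-0.18, adjusted p = 0.63), STOP1 (-0.22, adjusted p = 0.53) and CML24 (0.38, adjusted p = 0.82) did not pass.

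Glutathione transferase genes had a median interaction of -0.51, with 2 of 26 passing below 0 (6 over the list alone; camera adjusted p = 4.9e-05, adjusted p = 0.55 with an estimated correlation). Xyloglucan and expansin genes had a median of 0.41, with 1 of 20, XTH4, passing (4 over the list alone; camera adjusted p = 0.0032, adjusted p = 0.55 with an estimated correlation). Abscisic acid and cold genes had a median of -0.32, with 0 of 17 passing (2 below 0 over the list alone; camera adjusted p = 0.0043, adjusted p = 0.78 with an estimated correlation). The other 18 lists were not called and had no member past the test over all genes. Medians and camera adjusted p-values were 0.88 and 0.066 for shoot markers, -0.23 and 0.070 for aluminium-resistance genes, -0.38 and 0.089 for WRKY factors, 0.97 and 0.098 for jasmonate, -0.16 and 0.098 for endodermis and root cap, 0.21 and 0.18 for iron, -0.21 and 0.18 for nitrate, 0.25 and 0.23 for root hairs, 0.11 and 0.25 for phenylpropanoids, and 0.11 and 0.30 for the cell cycle. For the rest they were 0.27 and 0.32 for salicylate, 0.30 and 0.35 for ethylene, -0.26 and 0.38 for DNA damage, -0.11 and 0.38 for xylem and phloem, 0.17 and 0.38 for phosphate, 0.17 and 0.45 for calmodulin-like genes, 0.00 and 0.56 for heat shock, and -0.05 and 0.71 for auxin, whose mean was 0.07 with an upward camera direction.

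Counts of positive and negative interactions were 269 and 213 without wild-type control replicate 1, 67 and 226 without replicate 2, 2 and 10 without wild-type Al replicate 1, 4 and 12 without replicate 2, 5 and 24 without cml24-2 control replicate 1, 5 and 21 without replicate 2, 6 and 19 without cml24-2 Al replicate 1, and 2 and 11 without replicate 2. Lists called besides were jasmonate (adjusted p = 1.4e-04), shoot (0.0018), ethylene (0.0058), iron (0.010), salicylate (0.010), phenylpropanoid (0.020), calmodulin-like (0.036) and aluminium-resistance genes (0.041) without wild-type control replicate 1, WRKY (1.8e-07) and nitrate genes (0.011) without replicate 2, and shoot genes (2.0e-04) without wild-type Al replicate 1. Others were nitrate (0.018) and jasmonate genes (0.048) without cml24-2 control replicate 1, iron (0.0066), shoot (0.025), aluminium-resistance (0.045), phenylpropanoid (0.045) and WRKY genes (0.049) without replicate 2, and phosphate (8.9e-04), endodermis and root-cap (0.021), jasmonate (0.021) and cell-cycle genes (0.042) without cml24-2 Al replicate 2. The xyloglucan and expansin call was lost without wild-type control replicate 2 (adjusted p = 0.076), and wild-type control libraries were further apart than the others, with 865 genes over 2-fold apart against 331 to 360 in the other groups.

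**Figure D4:**
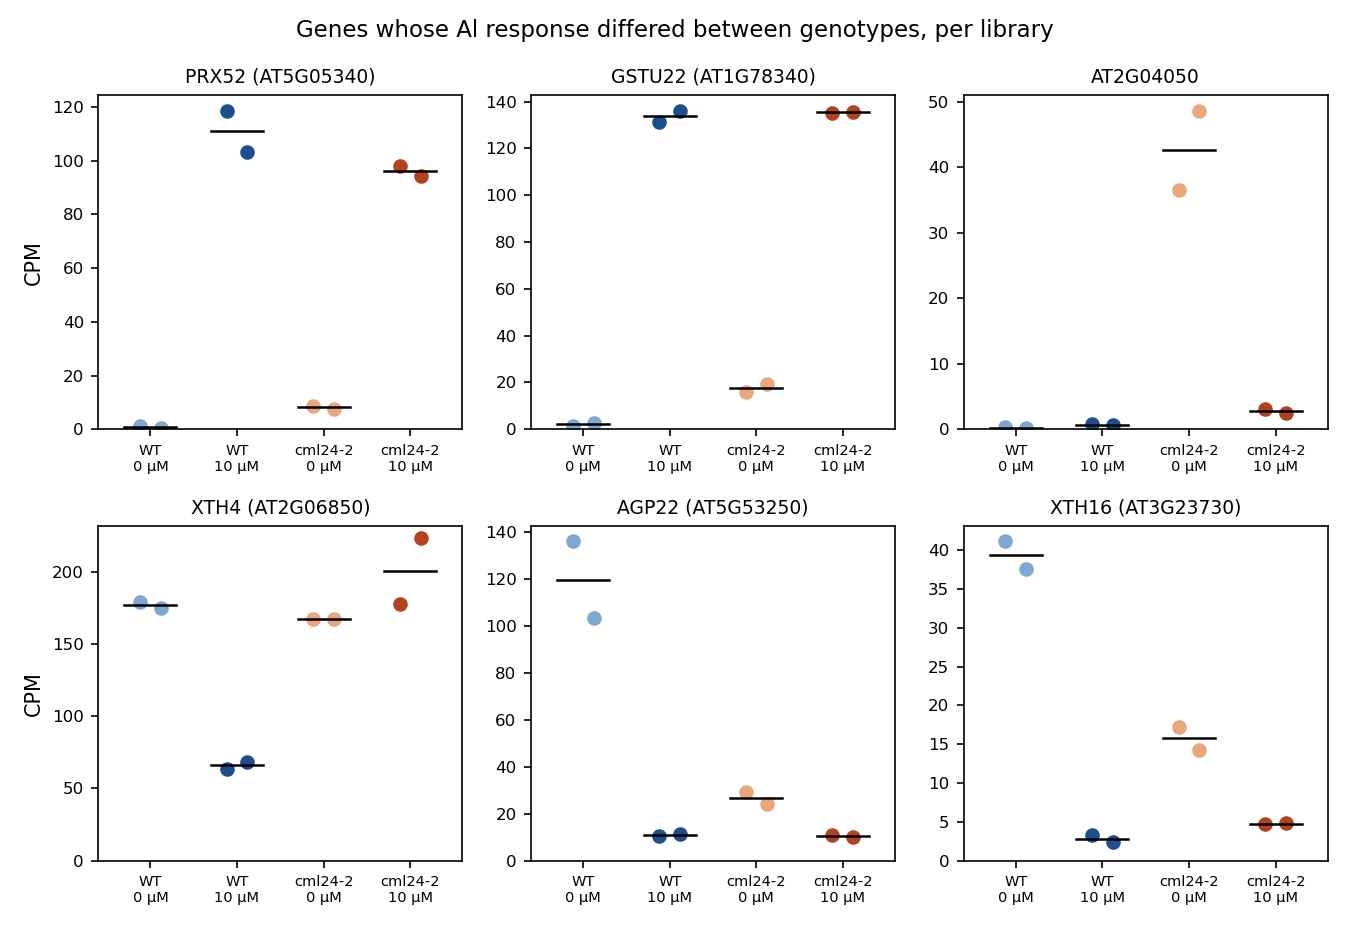
CPM per library of 6 genes whose response to Al differed between the genotypes. Points are libraries and bars are group means, n = 2.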

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

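The tests that weigh explanations here were all chosen after the results were seen. The genes and lists were picked out because their response to Al differed between the genotypes by the test of the interaction itself, n = 2 libraries a group.

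There were 20 genes with a positive and 41 with a negative interaction. The largest positive log2 values among genes that met the FPKM minimum were 3.12 for AT4G11190 and 2.26 for MSRB6, a methionine sulfoxide reductase. AGP22 was at 2.12, XTH16 at 2.07, AT3G06990 at 2.06 and XTH4 at 1.69. The negative ones included AT2G04050, of the MATE efflux family, at -5.45, AT5G46130 at -4.76, UGT74E2, an auxin glucosyltransferase, at -4.56, NAC011 at -3.76 and PRX52 at -3.52. AT3G10113 had a fitted value of -10.75, which rests on 0 counts in the wild-type controls and is no bound. Counts of AT3G06990, AT2G04050, UGT74E2 and AT3G10113 were partly shared with other genes. The call of PRX52 survived each left-out library, while each of the others was lost without at least 1. List medians were 0.41 for xyloglucan and expansin genes, -0.51 for glutathione transferase and oxidative-stress genes and -0.32 for abscisic acid and cold genes.

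Genes that differed between the wild-type control libraries were higher in cml24-2 than in wild type. There were 88 genes over 4 times higher in wild-type control replicate 2 than in replicate 1, with a mean of 5 CPM or more over all 8 libraries. Their median log2 difference was 1.59 without Al, which the pick of a low replicate 1 itself raises, and 0.78 against replicate 2 alone. A low wild-type control replicate 1 as the only cause is argued against by the comparison with Al, whose fold changes do not use that library. There the median of these genes was 2.44 (quartiles 1.73 to 3.06) and 86 of 88 were higher, 40 of them called. The CPM minimum counts the cml24-2 libraries too, however. Genes low in wild type could pass through them, which favours genes higher in cml24-2. Handling at harvest could not be told apart from the genotype, since no label gives harvest or batch, and the WRKY list differed by a median absolute log2 value of 0.90 between the wild-type controls against 0.11 to 0.30 within the other groups. An effect of the genotype itself stays open and was not tested.

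A set of 77 genes differed over 4-fold between the genotypes both without and with Al, 58 higher and 19 lower in cml24-2. A segment linked to CML24 on chromosome 5 is argued against as the main cause, as 5 of the 77 lay within 500 tested genes on either side, 6.49% (exact 95% interval 2.14 to 14.5%, 3.80 expected, Fisher's exact two-sided p = 0.43). Reads shared between near-identical copies are also argued against as the main cause, with 11 genes or 14.3% affected (7.35 to 24.1%) against 10.7% of all genes tested. WRKY46, WRKY18 and WRKY48 were among the 77. Their list differed more between the wild-type controls than between the libraries of any other group. Handling at harvest, a second mutation or a background difference elsewhere, and an effect of the genotype itself, stay open and were not tested.

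Without Al, log2 differences of cml24-2 from wild type went with the wild-type response to Al, with a covariance of 0.0901, 668 genes called higher in both, 632 lower in both and 158 and 266 in opposite directions. Both comparisons use the wild-type controls. In simulations with no true change this sharing gave a mean correlation of 0.498. All simulated differences are noise, so this value does not compare with the observed 0.290. The simulated covariances were at most 0.0152, with 1 spread per gene pooled over all groups. The spread between the 2 controls themselves puts the covariance from sharing higher, at 0.0277, an estimate from 1 pair of libraries. Splits with a different control library on each side gave 0.0876 and 0.0373, against sharing as the only cause, but it stays open with just these splits. A low wild-type control replicate 1 as the only cause is not borne out by a covariance of 0.104 with replicate 2 alone, above the 0.0554 variance of 1 control library, but it stays open because both comparisons then share the error of 1 library. An effect of the genotype itself stays open and was not tested.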

How the results depend on the processing

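No called named value changed sign under any alternative, no called list changed direction with a library left out, and no gene called in both fits had opposite signs. Results not called did change: 45 of 6910 named values took the other sign, and with 1 library left out 31 of 840 list tests changed direction and 26 list medians changed sign. Jasmonate genes with Al in wild type had a median of -0.77 without wild-type control replicate 1 and 0.76 without replicate 2. Both fits use the same wild-type Al libraries, so the sign followed the control library that was kept. Why the 2 controls differed was not tested. Of 435 named values under 16 alternatives, 6267 kept their side of the threshold, 622 lost the call and 21 gained it. Of the counts, 154 stayed within 1.5 times and 54 moved further. With DESeq2, genes higher in cml24-2 without Al went to 987, and positive and negative interactions to 74 and 125, and the cause was not tested. DESeq2 kept 8197 of 10327 calls for Al in wild type and 6901 of 9030 in cml24-2, 1629 of 2616 between the genotypes without Al, 1118 of 1607 tested there with Al, and 57 of 57 tested there for the interaction. With only the 4 libraries compared, which estimates the spread from those samples alone, the genotype calls were 481 higher and 407 lower without Al and 1894 and 1446 with Al. They kept 873 of 2604 calls tested there without Al and 1606 of 1610 with Al. The same cut in samples thus lowered the calls in 1 comparison and raised them in the other, so fewer samples alone do not account for it. The wild-type controls, the pair furthest apart, enter the comparison without Al and not the one with Al. With an estimated correlation, 0 lists were called for Al in wild type, 0 for Al in cml24-2, 0 and 0 between the genotypes without and with Al, and 0 for the interaction, against 10, 9, 10, 13 and 3 with the preset one. By construction the estimated form tests with the 4 residual degrees of freedom of the samples and the preset form with those of the genes, and the share of this and of the estimates in the change was not tested.

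Leaving out 1 library leaves a group with a lone sample, assumed to vary like the others. Genes higher and lower then ranged over 3844 to 4973 and 3907 to 5170 for Al in wild type, 3002 to 5114 and 3440 to 5108 in cml24-2, 516 to 1898 and 291 to 1309 between the genotypes without Al, 82 to 1591 and 66 to 1217 with Al, and 2 to 269 and 10 to 226 for the interaction. Fewer samples widen the error of the group concerned. The genotype comparison with Al takes no fold change from the wild-type controls. Its rise in counts without one of them therefore came through the fit shared by all libraries, which sets the spread, the scaling and the filter. The wild-type controls were the pair furthest apart, with 865 genes over 2-fold apart against 331 to 360 in the other groups. Which part of the shared fit acted, and why counts rose elsewhere, was not tested. Lists called ranged over 8 to 11, 8 to 14, 6 to 12, 11 to 14 and 3 to 11 in the same order, with 42 calls gained and 17 lost over the 840 tests, an alternative chosen after seeing the data. Counts of list members in all contrasts moved with these. The low-count filter was run again each time, so measured members differed, with 19 against 17 abscisic acid genes without cml24-2 Al replicate 1.

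Replicate numbers were not taken as pairs: deviations correlated at -0.02, -0.10, -0.17, -0.04, 0.04 and 0.14 between groups, and a block by number gave 5112 and 5206, 4293 and 4696, 1402 and 1129, 780 and 625, and 19 and 38 genes, with 10, 9, 10, 12 and 3 lists. At this depth and n, simulated changes of 1.5-fold in 67 genes were recovered in 19.4 to 26.9% in the pairwise contrasts. The share with as many genes changed as were called here was not tested.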

Other observations

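The groups of genes in this part, and the test of the idea on chloroplast transcripts, were chosen after their values were seen. WRKY40, MYB15 and ACS6 varied between libraries. They were among the 88 genes over 4 times higher in wild-type control replicate 2 than in replicate 1. So were LOX4 of the jasmonate list, CML37 of the calmodulin-like list and CBF2 of the abscisic acid and cold list. WRKY40 was at 3.57 and 46.0 CPM in the wild-type controls, 11.4 and 13.8 in wild type with Al, 127 and 70.2 in the cml24-2 controls, and 123 and 70.5 in cml24-2 with Al. In the same order, MYB15 was at 2.54, 42.2, 17.7, 18.7, 146, 86.7, 222 and 151 CPM, and ACS6, an ethylene synthesis gene, at 18.4, 125, 51.3, 52.9, 252, 143, 248 and 156 CPM. Transcripts of the seed-storage cruciferins CRA1, CRB and CRU3 had 403, 57 and 355 counts in cml24-2 Al replicate 1 and at most 2 in any other library. That library is 1 of the 2 behind every value of cml24-2 with Al, and whether it held other tissue was not tested.

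A few further genes were higher in cml24-2. ACC2, a plastid acetyl-CoA carboxylase whose counts were partly shared with other genes, differed by 3.41 without and 2.55 with Al on the log2 scale (SE 0.13 and 0.13, edgeR adjusted p = 4.6e-06 and 1.0e-04, n = 2). EMB1030, an alanyl-tRNA synthetase, differed by 3.71 and 1.71, and NUC-L2, a nucleolin, by 2.70 and 1.42. The hypothesis that these go with a changed level of chloroplast transcripts was tested on 42 chloroplast-encoded genes. Their median log2 difference was 0.77 without Al (quartiles 0.47 to 1.04, 9 rose) but -0.14 with Al (quartiles -0.38 to 0.15, 2 fell). The 3 genes stayed higher with Al, so a change of chloroplast transcripts in both comparisons was not seen. All 3 differences were smaller with Al, however, and EMB1030 had a called interaction (-2.01, SE 0.17, edgeR adjusted p = 0.0026). Whether that drop goes with the chloroplast transcripts was not tested. From means of log2(CPM + 1), another scale, the median was 0.53 without Al and -0.06 with Al when all libraries of the comparison were kept. With single libraries left out it ranged from 0.49 to 0.68 without Al and from -0.28 to 0.21 with Al, the last without wild-type Al replicate 2. Summed chloroplast transcripts were at 462 and 540 CPM in the wild-type controls, 561 and 983 in wild type with Al, 736 and 628 in the cml24-2 controls, and 554 and 625 in cml24-2 with Al.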
